A study of Homo sapiens with 6 samples.

How the data were processed

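Total RNA of 6 Mac1 cultures, 3 given the empty vector and 3 given shEZH2, was amplified and labelled with Cy3 and hybridised to single-colour Agilent arrays, per the labels' protocols. The scanner's intensity values for each spot were deposited as written by Agilent Feature Extraction 10.7.1.1, per the file headers (the submitters' processing notes give version 10.7). The processed intensity used here was background-subtracted on each array by that program and not normalized between arrays, per the file headers. The files also give the raw mean intensity, the local background intensity and 0 or 1 marks for spots well above background, saturated or outlying. The submitters' processing notes also name limma, with no role. The authors' value table holds log2 values with nearly equal distributions, and their normalization is not given in the sources used here. Between 99.89% and 99.95% of its values lay within 0.05 of the quantile-normalized log2 processed intensity, without centring of genes, and its column medians were 5.57, 5.575 and 5.574 for the controls and 5.573, 5.559 and 5.581 for shEZH2. Probe coordinates are those of the files, on hg19. Whether a probe lies in an exon or an untranslated region was not annotated here.

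The log2 processed intensity of each array was centred on its 75th percentile over non-control probes. Between 89 and 158 outlier-flagged spots per array were left out, none was saturated, and spots of a probe were averaged. A probe was kept if it was well above background on at least 3 of the 6 arrays, where a probe with several spots counted if at least 0.5 of them were. That kept 27910 of 41000 probes. Gene names were updated through the accession for 27294 probes, through the symbol for 2383 and through an older symbol for 454, and 10869 probes kept the name in the files. Each gene was represented by its kept probe of highest mean, which gave 19990 genes, 14231 of them with a present symbol. On each array between 25219 and 29290 probes were well above background.

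The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariates, shEZH2 minus control, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 fold changes are given with limma's standard error (SE). For single genes the exact two-sided permutation test of 3 against 3 values cannot go below 0.1. The 36 gene lists, with 728 genes in all, were fixed before the data were examined, as were the test, the filter, the naming rule and most alternatives. They were tested with limma's camera at a preset correlation of 0.01 on the genes with all 6 values, again with an estimated correlation, and with fry. Benjamini-Hochberg adjustment ran over the lists with at least 5 measured members. The list of genes reported as EZH2-repressed and the chemokine list both hold CXCL10, which was known from the study, so their counts adjusted over the list alone are not independent evidence for it.

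The genes named are EZH2 and the other measured PRC2 members, CXCL10, up to 2 members with the smallest p of each list described, and 10 genes each way. The last were to be the largest changes past the threshold with non-overlapping groups. As none passed, they are the 10 with the smallest p, and the conditions on symbol and overlap were retained, a decision taken after the top of the ranking had been seen. The rule for probes with several spots, the updating of symbols and the restriction of camera to complete genes were also set after the data had been seen.

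Both slides held both groups, so values with slide as a block and within each slide are given. As each slide holds equal numbers of control and shEZH2 arrays, the block left the fold changes of complete genes as they were and altered their errors. Alternatives covered background correction by normexp (offset 50), quantile and median scaling, the authors' value table, the filter on dim probes, the choice of probe, the outlier marks, slide, replicate number, array weights, a trended and robust eBayes, a 2-fold minimum, and each array left out. Removal of each array's trend with probe GC content (a spline with 4 degrees of freedom) was added after the data had been seen.

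The tests were checked on simulated data with the measured means and spreads of 19924 genes and independent genes, comparing shEZH2 against vector control. They called 2% of 2-fold, 58% of 4-fold and 100% of 8-fold and 16-fold changes, with 9 false calls among 139. At each size 50 changed genes were planted, which makes the adjusted threshold easier to pass than with few changes. Differences between arrays shared across genes were not simulated. The rates therefore do not give the power in the measured data, where EZH2 was 4.68-fold lower at a limma adjusted p of 0.9999. A lack of calls there is thus not evidence against large changes. In the measured data the median residual SD was 0.41 on the log2 scale. The limma p-values of single genes set the group difference against the spread between the 3 arrays of each group. Where slide was not a block, that spread includes any difference between slides as well as between cultures. Camera at the preset correlation compares a list with the other genes and treats its members as nearly independent. Its p-values therefore do not rest on the spread between cultures alone.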

Results

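Gene expression was measured in Mac1, an established line of malignant T cells from primary cutaneous anaplastic large cell lymphoma (PCALCL), a CD30-positive lymphoma of the skin. The comparison asked which transcripts differed when EZH2, the histone methyltransferase of Polycomb repressive complex 2 (PRC2), was targeted by a short hairpin RNA (shEZH2). Cells transfected with the empty vector were the control. RNA was taken 96 h after transfection, with 3 biological replicates per group per the series' design text and 1 single-colour Agilent array per replicate. Between 61.51% and 71.44% of the 41000 probes were well above background on an array. Slide 1 held vector control 1 and 2 and shEZH2 1 and 3, and slide 2 held vector control 3 and shEZH2 2. Levels below are log2 signals relative to the 75th percentile of the same array, and the number of arrays, 3 per group, limits their precision.

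**Figure D1:**
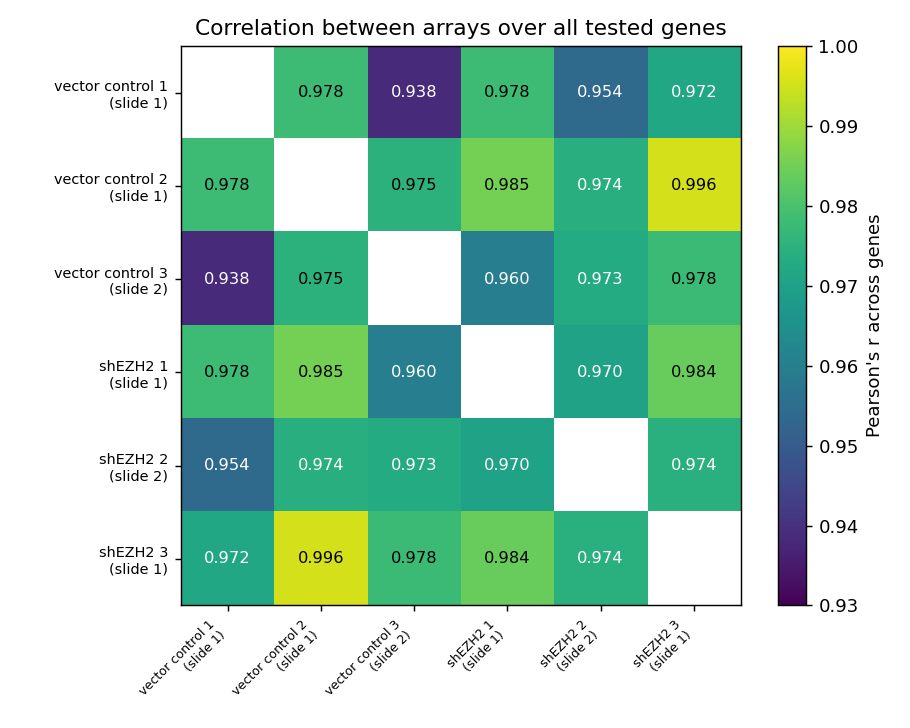
Pearson's r across the tested genes between each pair of arrays (both axes list the 6 arrays with their slide, colour scale from 0.93 to 1). The closest pair, at 0.9955, joined vector control 2 and shEZH2 3, and the farthest, at 0.9384, joined vector control 1 and vector control 3.

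EZH2 itself was lower in the cells given the hairpin. Its probe (chromosome 7, 148504521 to 148504580, minus strand, hg19) averaged 3.17 ± 0.55 in the controls and 0.95 ± 0.73 with shEZH2 (SD, n = 3 each), a 4.68-fold lower level. The log2 fold change was -2.23 with a standard error of 0.45. The 3 control arrays read 2.54, 3.46 and 3.52, and the 3 shEZH2 arrays read 1.12, 0.15 and 1.57. The difference was -1.65 within slide 1 and -3.37 within slide 2, and -2.23 with slide as a block. The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 arrays allow. EZH2 passed limma's test when adjusted over the list alone, the 11 measured PRC2 genes (adjusted p = 0.0153), and did not pass over all 19990 genes tested (adjusted p = 0.9999).

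No other PRC2 gene passed either adjustment. EED, the subunit that binds the methylated histone, had a log2 fold change of -0.14 (SE 0.25), and SUZ12, the core scaffold, one of 0.11 (SE 0.34, with other probes from -0.082 to 0.38). EZH1, the paralogous methyltransferase, stood at 0.25 (SE 0.23). RBBP4 and RBBP7, the histone-binding subunits, stood at -0.54 (SE 0.28) and -0.26 (SE 0.24), although the other RBBP4 probes ranged from -0.46 to 0.0013. Among the accessory subunits, JARID2, AEBP2, PHF1, MTF2 and PHF19 lay between -0.27 (PHF19, with a second probe at -0.16) and 0.27 (MTF2). As a list the PRC2 genes did not shift by limma's camera test (median -0.035, adjusted p = 0.167, or 0.714 with an estimated correlation), but passed as lower with normexp and 75th percentile scaling (0.00382).

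CXCL10, a chemokine that attracts activated T cells through CXCR3, had the smallest p of all genes tested. It had been named for reporting before the data were examined, because the study is known to have followed it. Its probe (chromosome 4, 76942934 to 76942993, minus strand, hg19) averaged 1.24 ± 0.29 in the controls and 3.33 ± 0.36 with shEZH2 (SD, n = 3 each), a 4.25-fold higher level, and was well above background on all 6 arrays. The log2 fold change was 2.09 (SE 0.30). It was 1.75 within slide 1 and 2.77 within slide 2, and 2.09 with slide as a block. CXCL10 passed when adjusted over the list alone, both among the 18 measured chemokines and among the 18 measured genes reported elsewhere as repressed by EZH2 in cancer (adjusted p = 0.00289 in each). It did not pass over all genes (adjusted p = 0.9999). The second chemokine by p was CCL1, with a log2 fold change of 1.18 (SE 0.33) and an adjusted p of 0.0699 over that list. The chemokines as a list did not shift (median 0.055, camera adjusted p = 0.111, or 0.714 with an estimated correlation), and neither did the genes reported as EZH2-repressed (median 0.057, adjusted p = 0.0757, or 0.714 with an estimated correlation). The second list did pass as higher with quantile normalization (adjusted p = 0.027), normexp and quantile (0.00717), the authors' value table (0.0253), probes detected on all 3 arrays of a group (0.0364), array weights (9.24e-05) and without vector control 1 (0.0113). The chemokine list passed as higher with normexp and 75th percentile scaling (0.0477) and without a filter on dim probes (0.0185). Over all alternatives the adjusted p of the EZH2-repressed list ran from 9.24e-05 to 0.923 and that of the chemokine list from 0.0185 to 0.923.

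**Figure D2:**
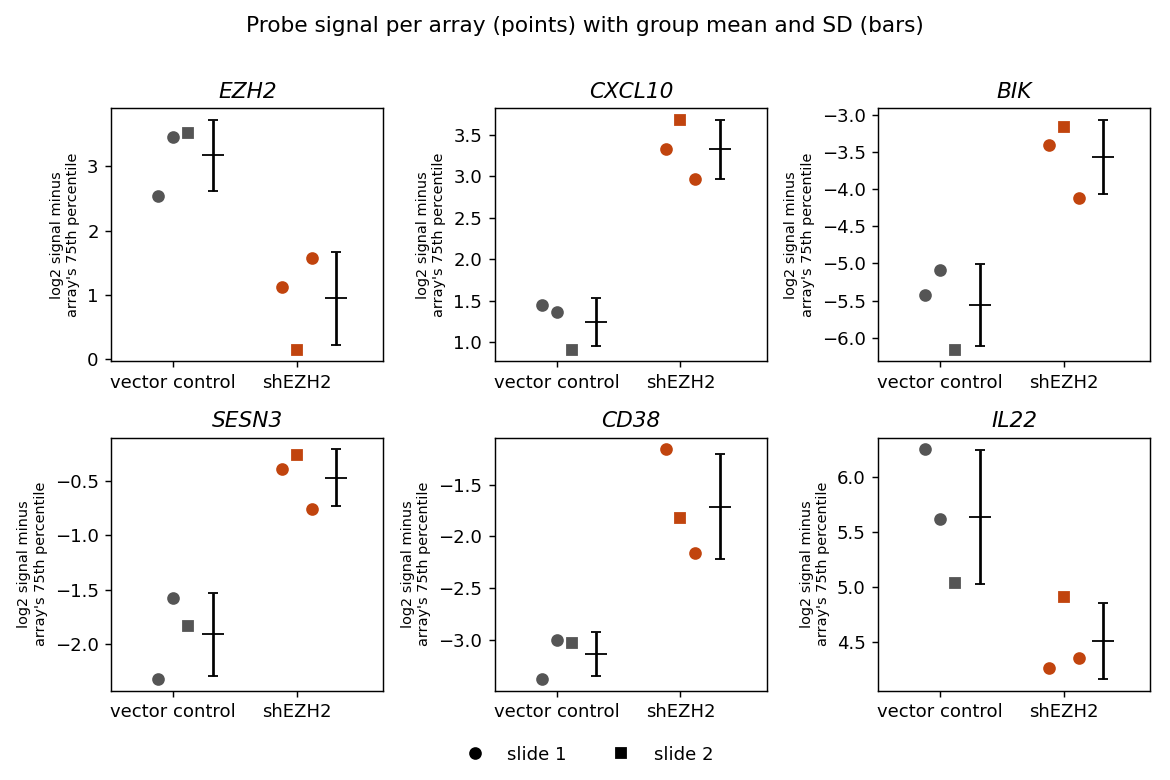
Signal of 6 named genes on each array, as log2 signal minus the array's 75th percentile (vertical axes, which do not start at 0), for the vector control and shEZH2 groups; points are arrays (circles slide 1, squares slide 2), and bars give the group mean and SD of 3 arrays. EZH2 lay between 2.54 and 3.52 in the controls and between 0.15 and 1.57 with shEZH2, while CXCL10 lay at 1.45 or below in the controls and at 2.97 or above with shEZH2.

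No gene passed limma's test over all 19990 genes at an adjusted p under 0.05, so the genes named next are given as values, taken by smallest p among those whose groups did not overlap. At an unadjusted p under 0.05 there were 310 genes, 233 higher and 77 lower with shEZH2, against 1000 expected by chance. The groups did not overlap in 1177 genes (5.91%), where chance gives 10% for 3 against 3. After CXCL10, the leading higher gene was BIK, a pro-apoptotic member of the BCL2 family (chromosome 22, 43525495 to 43525554, plus strand, hg19). BIK averaged -5.56 ± 0.55 in the controls, where 1 of 3 arrays was well above background, and -3.56 ± 0.50 with shEZH2 (SD, n = 3 each). Among the 34 measured apoptosis regulators it was the only gene that passed when adjusted over the list alone (log2 fold change 1.99, SE 0.39, adjusted p = 0.0384). That adjustment did not account for the other lists tested in the same way, and BIK was named here for its small p over all genes. The pass is therefore no separate evidence for a change in BIK. With normexp and 75th percentile scaling its log2 fold change was 1.02, and 0.35 with normexp and quantile normalization. That list as a whole did not shift (median -0.022, adjusted p = 0.989, or 0.996 with an estimated correlation), but passed as lower with normexp and 75th percentile scaling (0.000299).

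SESN3, a stress-responsive sestrin (chromosome 11, 94898874 to 94898933, minus strand, hg19), was 2.71-fold higher (log2 fold change 1.44, SE 0.30), and its other 2 probes gave 1.42 and 1.48. CD38, a surface enzyme that consumes NAD, was 2.67-fold higher (1.42, SE 0.32), with 1.53 within slide 1 and 1.20 within slide 2. CRACDL was 2.97-fold higher (1.57, SE 0.31), CXXC5, which encodes a zinc finger protein, 2.85-fold (1.51, SE 0.36, with a second probe at 0.72) and RAB40B, a small GTPase gene, 2.57-fold (1.36, SE 0.33). HHAT, which encodes the acyltransferase of Hedgehog ligands, and SLC2A6, a member of the glucose transporter family, were each well above background on 1 of 3 control arrays, with log2 fold changes of 1.55 (SE 0.35) and 1.82 (SE 0.41). MBD5 was not well above background on any control array and was at least 2.13-fold higher in the main setting. Such bounds set the brighter group's mean against the lowest signal well above background on each dim array, or the probe's own signal where higher. By the naming rule, all of these had a higher value on each shEZH2 array than on any control array. A higher value with shEZH2 on both slides follows from that rule and is no added support. With normexp and quantile normalization the log2 fold changes stayed positive but shrank by over 1.5 times, to 0.90 for SESN3, 0.69 for CD38, 0.80 for CRACDL, 0.92 for CXXC5, 0.62 for RAB40B, 0.28 for HHAT, 0.32 for SLC2A6 and 0.21 for MBD5, the last below its bound.

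Below EZH2, several of the lower genes were dim. BZW2 (chromosome 7, 16746044 to 16746103, plus strand, hg19) was bright and tight, at 4.45 ± 0.12 in the controls and 3.67 ± 0.22 with shEZH2 (SD, n = 3 each), a 1.71-fold lower level. IL22, the interleukin made by activated T cells, averaged 5.64 ± 0.61 in the controls and 4.51 ± 0.35 with shEZH2 (SD, n = 3 each), a log2 fold change of -1.13 (SE 0.37) that was -1.62 within slide 1 and -0.13 within slide 2. HOXB2, a homeobox gene, was not well above background on any shEZH2 array and was at least 2.83-fold lower. The same held for NRG3, a neuregulin, at least 1.33-fold lower, and for the brightest probe of DKK3, a secreted Dickkopf protein, at least 2.05-fold lower. The log2 fold changes of POTEG (-1.80, SE 0.56) and OR6Y1 (-2.02, SE 0.67) came from probes detected on 1 and 2 of 3 shEZH2 arrays. LGI4 stood at -3.32 (SE 1.05) and CFAP74, whose probe was detected on 2 of 3 shEZH2 arrays, at -3.13 (SE 1.03), with an SD of 2.40 and 2.34 among the controls. Across the alternatives these ran from -4.61 to -0.75 for LGI4 and from -4.37 to -0.65 for CFAP74. DKK3, HOXB2, NRG3, POTEG and OR6Y1 turned to higher values with shEZH2, between 0.29 and 0.63, in 1 setting, normexp and 75th percentile scaling, which moved the median of all genes by 0.24. All 5 stayed lower in every other setting that tested them, normexp and quantile normalization included.

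G2/M, G1/S and MYC and ribosome biogenesis genes were lower as groups with shEZH2 by camera with a preset correlation of 0.01, and no list of the 36 passed with an estimated correlation. The estimated correlations were 0.536 for G2/M, 0.153 for G1/S and 0.4 for MYC, far above the preset value. Of the 33 measured G2/M and mitosis genes, 32 had a negative log2 fold change (median -0.34, adjusted p = 8.4e-07, or adjusted p = 0.714 with an estimated correlation). CDC20, the activator of the anaphase-promoting complex, stood at -0.66 (SE 0.31), and UBE2C, its ubiquitin-conjugating enzyme, at -0.51 (SE 0.27). Of the 35 G1/S and DNA replication genes, 29 were negative (median -0.19, adjusted p = 0.00771, or adjusted p = 0.714 with an estimated correlation), among them the replication factors GINS2 at -0.55 (SE 0.26) and MCM2 at -0.72 (SE 0.36). Of the 23 MYC and ribosome biogenesis genes, 19 were negative (median -0.21, adjusted p = 0.0235, or adjusted p = 0.792 with an estimated correlation), including SRM, spermidine synthase, at -0.50 (SE 0.27) and BOP1, a ribosome assembly factor, at -0.59 (SE 0.34). No single member of these lists passed, over all genes or over the list alone. The G2/M median was -0.10 within slide 1 and -0.95 within slide 2 (block adjusted p = 2.39e-06), the G1/S median -0.0061 and -0.40 (block 0.0192) and the MYC median -0.19 and -0.40 (block 0.0423). Without shEZH2 2 the G2/M median was -0.081 and its call was lost (adjusted p = 0.0941). The G1/S call was lost without vector control 2 (0.0543), vector control 3 (0.879) or shEZH2 2 (0.086), where the medians were -0.18, -0.13 and -0.089. It passed with larger medians without vector control 1 (-0.30, adjusted p = 8.09e-06) or shEZH2 3 (-0.31, 0.00257). The MYC call was lost without vector control 2 (median -0.13, adjusted p = 0.123), vector control 3 (-0.078, 0.972) or shEZH2 1, where the median turned to 0.029 (0.856). On slide 1 alone all 3 calls were lost (adjusted p = 0.921 for G2/M, 0.921 for G1/S and 0.584 for MYC), and those of G1/S and MYC were also lost with quantile normalization (medians -0.12 and -0.17, adjusted p = 0.0581 and 0.114) and the authors' value table (-0.12 and -0.17, 0.0542 and 0.111). Normexp and quantile normalization ended the G1/S call (median -0.062, adjusted p = 0.0631). With normexp and 75th percentile scaling all 3 passed with larger medians, -0.58 for G2/M, -0.56 for G1/S and -0.73 for MYC, in a setting where the reference genes passed as lower too. Smaller medians passed for G2/M with normexp and quantile normalization (-0.20) and array weights (-0.19), and for MYC with normexp and quantile normalization (-0.10).

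Integrated stress response genes include ATF4, other stress factors and genes of amino acid transport and synthesis. They were lower as a group by camera with a preset correlation, and at that correlation the call held with each array left out. Of the 27 measured members, 23 had a negative log2 fold change (median -0.30, adjusted p = 1.98e-05, or adjusted p = 0.714 with an estimated correlation). SLC7A5 and SLC3A2, the light and heavy chains of the LAT1 amino acid transporter, stood at -0.66 (SE 0.25) and -0.69 (SE 0.28), and second probes gave -0.73 and -0.57. The median was -0.49 within slide 1 and -0.14 within slide 2 (block adjusted p = 1.92e-05). Without each array in turn it ran from -0.56 (without vector control 3) to -0.13 (without vector control 1), with adjusted p between 6.96e-08 and 0.0203. With normexp and 75th percentile scaling it was -0.75 (adjusted p = 3.14e-08). Heat shock genes were also lower by the same test, with 14 of 17 negative (median -0.23, adjusted p = 0.033, or adjusted p = 0.714 with an estimated correlation). STIP1, a co-chaperone, stood at -0.76 (SE 0.40), and HSPB1, a small heat shock protein, went the other way at 0.36 (SE 0.29). Across the alternatives HSPB1 ran from -0.25 to 0.57 and changed sign in 1 of them. The heat shock median was -0.12 within slide 1 and -0.28 within slide 2, and the call was lost with slide as a block (median -0.23, adjusted p = 0.0642). It was also lost without vector control 2 (median -0.23, adjusted p = 0.126), vector control 3 (-0.21, 0.476), shEZH2 1 (-0.12, 0.437) or shEZH2 2 (-0.27, 0.0575), and on slide 1 alone (0.576). It was lost with normexp and quantile normalization (-0.15, 0.133), and with a median about as large as before or larger with quantile normalization (-0.23, 0.131), the authors' value table (-0.23, 0.111), and the GC trend removed with slide as a block (-0.30, 0.0649). With normexp and 75th percentile scaling heat shock passed at -0.71 (adjusted p = 5.18e-05). Unfolded protein response genes did not pass (median -0.18, adjusted p = 0.1, or adjusted p = 0.714 with an estimated correlation), except as lower with normexp and 75th percentile scaling (2.32e-05).

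Adhesion, antigen presentation, interferon and p53 target genes were higher as groups with shEZH2 by camera with a preset correlation, and none passed with an estimated correlation. All 4 tests turned to lower in 1 setting, normexp and 75th percentile scaling. There antigen presentation passed as lower (median -0.35, adjusted p = 0.0027), as did the reference genes (-0.68, 0.00022), while adhesion (-0.20, 0.559), interferon (0.061, 0.608) and p53 targets (-0.0087, 0.27) did not pass. With normexp and quantile normalization all 4 stayed higher (adjusted p = 0.000249, 5.86e-08, 0.00192 and 0.0039). Of 21 measured adhesion and migration genes, 17 had a positive log2 fold change (median 0.25, adjusted p = 0.00231, or adjusted p = 0.714 with an estimated correlation). VCAM1, a vascular adhesion molecule, stood at 0.90 (SE 0.26) and TIMP2, a metalloproteinase inhibitor, at 0.70 (SE 0.30). Of 24 antigen presentation genes, 18 were positive (median 0.15, adjusted p = 0.0134, or adjusted p = 0.792 with an estimated correlation), with the class II genes HLA-DQA1 at 0.65 (SE 0.25, with a second probe at 0.28) and HLA-DRA at 0.47 (SE 0.25). Of 40 interferon response genes, 31 were positive (median 0.20, adjusted p = 0.0173, or adjusted p = 0.714 with an estimated correlation), with the transcription factor IRF1 at 0.48 (SE 0.28) and the guanylate-binding protein gene GBP1 at 0.50 (SE 0.30, with a second probe at 0.32). Of 29 p53 targets, 19 were positive (median 0.24, adjusted p = 0.0374, or adjusted p = 0.792 with an estimated correlation), with RRM2B, a ribonucleotide reductase subunit, at 0.68 (SE 0.34) and TP53INP1 at 1.17 (SE 0.67). No member passed over all genes or over its list alone.

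Within slide 1 and slide 2 the adhesion median was 0.24 and 0.27 (block adjusted p = 0.00303) and the interferon median 0.099 and 0.35 (block 0.0192). The antigen presentation median was -0.087 within slide 1 and 0.63 within slide 2 (block 0.0233), and the p53 target median -0.11 and 0.75 (block 0.0428). The reference genes had opposite signs by slide as well, with medians of -0.31 and 0.27. The adhesion call was lost without shEZH2 1 (median 0.13, adjusted p = 0.226), and its median was as small without vector control 3 (0.13, 0.021), where the call held. The interferon call was lost without vector control 1 (median 0.17, adjusted p = 0.48) or shEZH2 2 (0.070, 0.847). The antigen presentation call was lost without vector control 2 (median 0.17, adjusted p = 0.119), vector control 3 (-0.066, 0.83) or shEZH2 2 (0.14, 0.0941). Its median also depended on vector control 1, without which it was 0.37 (8.09e-06). The p53 call was lost without vector control 1 (median 0.19, adjusted p = 0.0572), vector control 3 (0.079, 0.476) or shEZH2 2, where the median turned to -0.010 (0.907). On slide 1 alone the interferon (0.617), antigen presentation (0.955) and p53 (0.617) calls were lost. Array weights ended the interferon (median 0.026, adjusted p = 0.704) and p53 (-0.047, 0.895) calls. Testing without a filter on dim probes ended the adhesion call (0.17, 0.0815) and, with an unchanged median, the p53 call (0.24, 0.0712). The p53 median also stayed about as large where the call was lost with the mean of a gene's probes (0.24, 0.0898) and with the GC trend removed and slide as a block (0.21, 0.0663). The p53 call held in 14 of 25 settings.

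**Figure D3:**
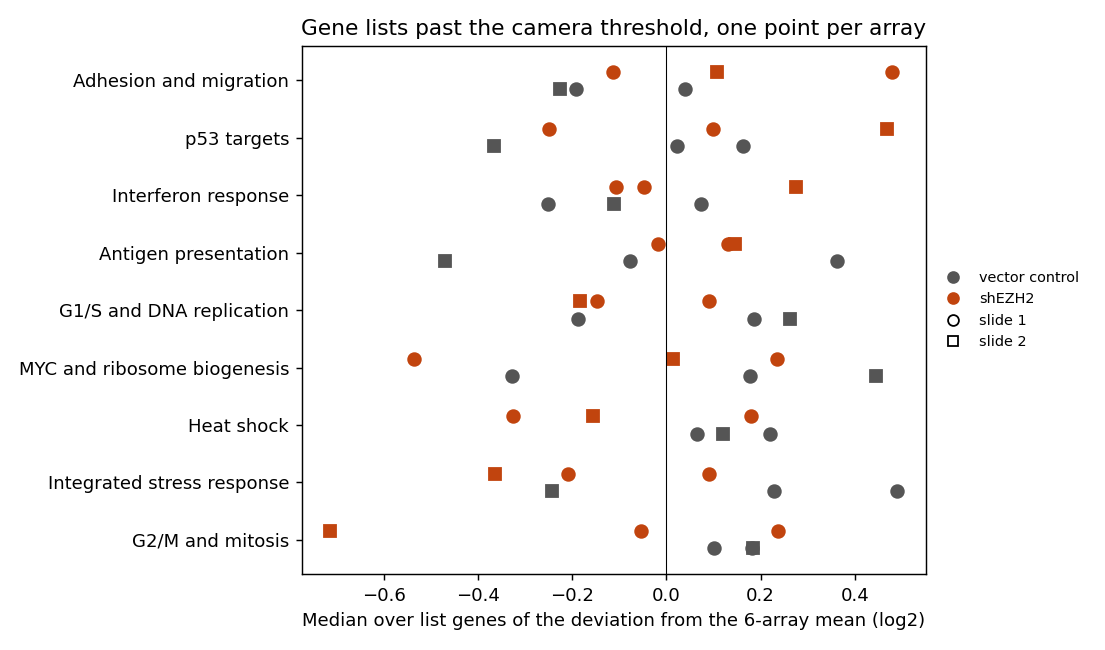
Median over the genes of each list of the deviation from the mean of the 6 arrays (horizontal axis, log2), for the 9 lists that passed camera with a preset correlation; each point is an array (grey vector control, orange shEZH2, circles slide 1, squares slide 2). For G2/M and mitosis the 3 controls lay between 0.10 and 0.18, and the shEZH2 arrays at 0.24, -0.71 and -0.055. In every list shown the groups overlapped.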

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

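The settings with the GC trend removed were chosen after the data were seen. No gene passed limma's test under any of the 23 planned and 2 added settings run over genes, with 18 to 2135 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.1101 (array weights). The EZH2 log2 fold change stayed negative throughout, from -2.54 to -1.63 (adjusted p 0.2099 to 1), and from -2.54 to -1.83 with each array left out. CXCL10 stayed between 1.45 and 2.27 (adjusted p 0.1101 to 1). Of 446 values of the 20 genes with the smallest p, 5 changed sign, all with normexp and 75th percentile scaling. The count of shifted lists, 9, became 18 with normexp and 75th percentile scaling, 5 on slide 1 alone, and 0 with an estimated correlation and with fry, and ran from 3 to 10 with each array left out (5 without vector control 2, 3 without shEZH2 2). Fewer arrays enter on slide 1 alone and with an array left out. The correlations estimated for the 9 lists ran from 0.0844 (interferon response) to 0.536 (G2/M), all above the preset 0.01, and camera's p-values rise with the correlation. Whether this accounts for the whole loss of calls was not tested, nor was the cause for the other settings. The setting with 18 moved the median of all genes by 0.24, and with it camera turned interferon response (median 0.061), antigen presentation (-0.35), NF-kB (-0.42), p53 targets (-0.0087) and adhesion (-0.20) to lower. Of these antigen presentation (adjusted p = 0.0027) and NF-kB (0.00283) passed as lower and the other 3 did not pass. The interferon median and test differed in sign. Camera sets a list against the other genes, and the median of all genes was 0.214 with normexp and 75th percentile scaling, above that of the interferon list. Slide 1 alone turned the G1/S test (-0.0061) and the p53 test (-0.11). With each array left out, medians of lists whose test turned ran as follows: p53 targets -0.010 to 0.35, MYC -0.43 to 0.029. The ribosomal protein list passed as higher without vector control 1 (0.24) and as lower without vector control 3 (-0.35), with a range of -0.35 to 0.24, and the cholesterol list, from -0.12 to 0.15, passed as higher without shEZH2 1. Over the 900 values of lists, 721 stayed on their side with the same direction, 57 lost a call, 28 gained one in the same direction, 11 turned with a call before or after, and 83 changed direction with no call in either. With the replicate number as a block, 0 genes passed, EZH2 stood at -2.23 and 9 lists passed. Arrays of the same number deviated from their group means with correlations of 0.46, -0.29 and 0.0057 across genes, so the numbers are not taken to pair the arrays, and by this measure vector control 2 and 3 correlated best with an shEZH2 array of another number. Probes tested separately gave no test of lists. Dim probes have only bounds in the group where they were not well above background.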

Other observations

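Of the tests in this part, the other splits for genes at an unadjusted p and for lists and the GC correction of CXCL10 were set before their result was seen, and the remaining tests only afterwards.

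The following groups of genes, fixed in advance, did not pass camera at the preset correlation. Mature T cell markers had a median log2 fold change of -0.062 over 22 genes (adjusted p = 0.671), with the kinase gene ZAP70 at -0.54 (SE 0.27). ALCL and cytotoxic markers had a median of -0.085 over 19 genes (adjusted p = 0.265), with GZMB, the cytotoxic protease granzyme B, at -1.04 (SE 0.49), a difference of -1.82 within slide 1 and 0.52 within slide 2. Developmental transcription factors, common Polycomb targets, had a median of 0.050 over 27 genes (adjusted p = 0.551), with LHX2 at 0.97 (SE 0.26). Markers of other cell types did not pass either: B cell (median -0.040, adjusted p = 0.75), myeloid (-0.37, 0.081), NK cell (-0.20, 0.357) and stromal, endothelial and epithelial (-0.091, 0.184). The B cell and stromal tests pointed higher although their medians were negative. The stromal list included the matrix gene FBN1 at 1.11 (SE 0.30). Cytokines stood at -0.18 over 22 genes (adjusted p = 0.295), with IL1A at -0.70 (SE 0.28). Under single alternatives the ALCL list passed as lower with normexp and 75th percentile scaling (adjusted p = 0.000242), the NK cell list as lower without shEZH2 3 (0.0358) and the stromal list as higher without a filter on dim probes (0.024). No single gene named here passed limma's test over all genes.

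Glycolysis and hypoxia genes had a median of -0.12 over 34 genes (adjusted p = 0.527), but this joined -0.41 within slide 1 and 0.52 within slide 2. Oxidative phosphorylation genes likewise had -0.28 and 0.53, and cytosolic ribosomal proteins -0.32 and 0.48. All 3 lists passed as lower with normexp and 75th percentile scaling (adjusted p = 3.2e-06, 2.02e-08 and 1.23e-08) and on slide 1 alone (1.33e-05, 0.00695 and 0.00239). Glycolysis genes also passed as lower with array weights (median -0.23, adjusted p = 0.00179) and without vector control 3 (-0.45, 7.19e-05). Vector control 1 and vector control 3 were far apart in such lists: the ribosomal median deviated by 0.53 and -0.59 and that of replication-dependent histones by 0.91 and -0.97. The reference genes deviated by 0.368 and -0.355 on those controls and had medians of -0.31 within slide 1 and 0.27 within slide 2. The opposite signs by slide were therefore not particular to these lists.

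Arrays of one group differed as much as arrays of different groups. The mean correlation across genes was 0.9699 for the 6 pairs within a group and 0.9744 for the 9 pairs between groups. The closest pair was vector control 2 and shEZH2 3 (0.9955), and the farthest was vector control 1 and vector control 3 (0.9384). Removing each array's trend with probe GC content took away 11.6% of the sum of squares within groups, and removing its trend with brightness took away 8.67%. Neither smooth trend by itself therefore accounts for most of it. The farthest pair had opposite GC trends: GC content correlated with the deviations at 0.377 on vector control 1 and -0.29 on vector control 3. The correction takes only what varies smoothly with probe GC, so other differences that accompany these trends were not tested. A slide term took 48.5%, more than any of the 8 other choices of 1 array per group in its place (highest 41.1%) and above the 25% that 1 of 4 degrees of freedom gives, so a slide or scan effect may contribute, but with 1 array of each group on slide 2 it cannot be told apart from a difference between cultures. The bound first set for this test was 50%, which the slide term narrowly missed, and the comparison with 25% and with other choices was set after that value was seen.

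CXCL10 was higher with shEZH2 on both slides, with 1 array against 1 on slide 2. Its controls lay at 1.45 or below and its shEZH2 arrays at 2.97 or above. That separation itself argues against slide or 1 deviating array as its whole cause. It also fixed the outcome of the tests of slide and of 1 array left out, which therefore add no separate support. The GC correction argues against probe GC content as its whole cause. The smaller difference within a slide was 1.75, the log2 fold change with the GC trend removed was 2.04 (SE 0.30), and the lowest value with 1 array left out was 1.91. The median of the interferon list was 0.203, below 1.04, which is 0.5 of the CXCL10 change, by more than the SD of the members (0.254). This speaks only against a general interferon response of like size. The list had 31 of 40 genes positive and passed as higher at the preset correlation (camera adjusted p = 0.0173, or 0.714 with an estimated correlation). A smaller interferon contribution was therefore not excluded. Whether CXCL10 responded to lower EZH2 or to another effect of the hairpin stays open, and a second hairpin or a rescue with EZH2, which would tell them apart, was not among the arrays.

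The lower G2/M and mitosis genes may rest on 1 array. Without shEZH2 2 the median was -0.0809 against -0.34 with all arrays, and the call was lost. EZH2 was lowest on that array (0.15). The array was on slide 2 and had the lowest share of probes well above background (61.51%). Vector control 3, on the same slide, deviated by 0.18 in this list. A stronger knockdown in that culture, an unrelated difference between cultures and a fault of the array all stay open.

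The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. In all 10 splits 0 genes passed, the real one included, and the highest of the others was 0. The real grouping gave 310 genes at an unadjusted p under 0.05, and the highest of the others gave 2849, with 7 of the 10 splits giving as many as the real one. The split with 2849 set vector control 1 and 2 and shEZH2 1, all on slide 1, against both slide 2 arrays and shEZH2 3. It gave several times the real count, which points to a structure among the arrays. For shifted lists the real grouping gave 9 and the highest of the others 16, and 4 of the 10 splits gave as many. No split into 3 and 3 follows the slides, which hold 4 and 2 arrays.

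LGI4 and CFAP74 differed among the controls in the same way. LGI4 read 0.91, -3.86 and -0.92 and CFAP74 0.51, -4.15 and -1.42 in vector control 1, 2 and 3, against shEZH2 values from -4.77 to -4.51 for LGI4 and from -5.03 to -4.69 for CFAP74. Both were singled out after their values were seen.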
